A study of Mus musculus with 24 samples.

How the data were processed

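Gene expression was measured in lung tissue of wild-type mice and of mice lacking interleukin 13 (IL-13 KO), each treated with HDM or PBS. There were 3 samples in each of the 4 groups, and every sample was hybridised to a pair of arrays, called set A and set B here, so that 24 arrays held 12 samples. Group, replicate number and the pairing of the arrays were read from the sample titles. Over the 100 probe sets present on both sets, the set A array of 8 of 12 samples correlated best with its own set B array, and that of 12 of 12 with an array of the same treatment. In wild-type HDM replicate 3 and KO PBS replicates 2 and 3 the best match had the other genotype (r with their own array 0.36, 0.23 and 0.26), so the pairing rests on the titles. The labels do not say that the samples of a group came from separate animals, so the p-values measure the spread between these samples, which can be technical. Dose, route, schedule, background strain, age and sex were not given in the sources used here.

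The deposited values were linear intensities, 1 per probe set and array, and all were above 0. The software that made them was not given in the sources used here. The mean after trimming 2% from each end was 150 on every one of the 24 arrays, so the authors had scaled each array to a common mean, and this scaling was kept. No detection calls were used here, so the number of arrays and the spread between them limit the precision. Median intensity ranged from 69.5 to 77.7 over the set A arrays and from 83.5 to 93.7 over the set B arrays. Spearman correlations between samples of a group were 0.962 to 0.98 on set A and 0.887 to 0.927 on set B, and no pair of arrays was identical.

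The intensities were converted to log2(value + pseudocount), with a pseudocount of 7 for set A and 11 for set B, the 10th percentile of each set's values. A fold change on this scale understates the change of genes with low signal. Control probe sets were left out, and the 100 probe sets present on both sets were tested on set A only. Probe sets with a mean under the 30th percentile of their set were left out, which corresponds to signals of about 32 on set A and 39.2 on set B. This left 15838 probe sets of set A and 15658 of set B, 31496 in all. Gene names came from the platform annotation given with the data: 20380 probe sets of set A and 14661 of set B had a single gene, 691 and 245 had several, and 1555 and 7605 had none. Of the single-gene probe sets, 20364 and 14499 matched a gene in the RefSeq table. Names were given only for probe sets with a single gene.

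Tests used limma 3.58.1 in R 4.3.3. One model with the 4 groups was fitted, leaving 8 residual degrees of freedom, followed by eBayes with an intensity trend and Benjamini-Hochberg adjustment over all 31496 probe sets within each comparison at 0.05. The comparisons were HDM against PBS in wild type, HDM against PBS in IL-13 KO, the difference between those 2 effects (the interaction, KO effect minus wild-type effect), KO against wild type after PBS, and KO against wild type after HDM. For gene-level counts and gene lists each of 14477 genes was represented by its tested probe set with the highest mean. Genes with probe sets called in opposite directions numbered 1 for the HDM effect in wild type, 5 for that in KO, 0 for the interaction and 1 in each comparison of KO with wild type, where it was Xaf1.

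Gene lists covered goblet cells and mucus, alternatively activated macrophages, chitinases, eosinophils, Th2 and airway cytokines and receptors, chemokines, T cells, B cells, plasma cells and immunoglobulins, neutrophils, macrophages, dendritic cells and MHC class II, mast cells and basophils, NK and cytotoxic cells, interferon response, complement and acute phase, extracellular matrix, cell cycle, club cells, ciliated cells, alveolar type 2 and type 1 cells, endothelium, smooth muscle, fibroblasts, cardiac muscle, skeletal muscle, adipose tissue, thymus, erythroid cells, immediate early and stress genes, circadian clock, arginine metabolism, and the neighbours of Il13 on chromosome 11. A further list of sex-linked genes served as a sample check and had 1 tested member, so 34 of the 35 lists were tested. Some lists share genes, so their results are not independent. For example, 12 of 22 alternatively activated macrophage genes and 3 of 5 chitinases, Chil4 among them, are also in other lists. The test was camera with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with a correlation estimated for each list, and fry, were run as alternatives.

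The groups, comparisons, lists, filter, pseudocount rule, alternative settings and the rule for naming genes were fixed before the data were examined. The rule named, per comparison, the 10 called genes with the largest rise and the 10 with the largest fall whose groups did not overlap (for the interaction, by the call alone), up to 4 called members of each list described, or up to 2 with the smallest p where none was called, and Il13, Il4, Il5, Il13ra1, Il13ra2, Il4ra and Stat6 in every comparison. RIKEN clones and predicted genes were counted under the rule and left out of the text. Scin, Aoc3, Aox3, Ahcyl2, Acta2, Evc2 and Synpo2 in the interaction, Tnnc2, and genes given in a comparison other than the one in which the rule named them were chosen after their values were seen. The alternatives were quantile normalization, a smaller pseudocount (the one used divided by 4), no filter, a filter at the 50th percentile, eBayes without trend, the replicate number as a block, set A alone, and leaving out each sample in turn. Further alternatives were chosen after seeing the data: leaving out the 3 wild-type samples in which Tnnc2, a fast skeletal muscle troponin, had a signal over 100, adding a skeletal muscle score to the model, and adding the log2 ratio of 5' to 3' actin signal.

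The procedure was tested on simulated data with known changes in about 200 probe sets. For the HDM effect in wild type it recovered 6.1% of changes of 0.5 (log2), 44.7% of changes of 1, 95.6% of changes of 2 and 91.1% of changes of 3. For the interaction it recovered 0% (0 of 49), 19.1%, 75.6% and 88.9%. In the list test a single list shifted by 0.5 was called with both settings of camera, and none of the others was. The simulated genes varied independently of each other, so the list test cannot show how often lists of correlated genes are called falsely. Figures were drawn with Python 3.11.15.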

Results

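Lung RNA was compared between wild-type mice and mice lacking interleukin 13 (IL-13 KO), each labelled HDM, the usual abbreviation of house dust mite, an allergen, or PBS, the usual abbreviation of phosphate-buffered saline. There were 4 groups with 3 samples each. IL-13 is a cytokine of type 2 immunity that acts on airway epithelium, smooth muscle and macrophages. The design asks which genes HDM changes in the lung, and which of these changes differ in mice without IL-13. In the set A arrays the first principal component held 45.4% of the variance.

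Il13 itself had very low signal in every sample. It ranged from 4.65 to 12.1 in wild type after PBS, 15.5 to 29.9 in wild type after HDM, 3.3 to 9.45 in KO after PBS and 8.71 to 15.5 in KO after HDM. The probe set lay under the filter, and whether it lies in the deleted part of the gene is not known here, so it does not check the genotype labels. Il5, which encodes the eosinophil growth factor, and Il13ra2, the decoy receptor of IL-13, were also under the filter. In wild-type PBS, wild-type HDM, KO PBS and KO HDM samples, in that order, mean signals were 8.52, 17.8, 11.1 and 23.7 for Il5 and 16.8, 50.4, 14.1 and 23.9 for Il13ra2 (n = 3 each). Il4, Il4ra, Il13ra1 and Stat6, the other members of this signalling pathway, were measured and were not called in any of the 5 comparisons. Skeletal muscle transcripts differed between samples: Tnnc2 had a signal of 413 in wild-type PBS replicate 2, 198 in wild-type HDM replicate 1 and 988 in wild-type HDM replicate 2, and below 10 in the other samples. The ratio of 5' to 3' actin signal, a measure of RNA integrity, was lowest in wild-type PBS replicate 2 (0.409 on set A and 0.349 on set B) and KO HDM replicate 1 (0.464 and 0.428). It was lower in the KO HDM group (0.464 to 0.656 on set A, 0.428 to 0.612 on set B) than in the wild-type HDM group (0.695 to 0.832 and 0.643 to 0.851), without overlap, so it differs along with the comparison of KO with wild type after HDM and with the interaction. The same ratio for Gapdh overlapped between these groups (1.04 to 1.16 and 1.09 to 1.16 on set A, 0.791 to 1.07 and 0.856 to 1.01 on set B).

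In wild-type lung HDM induced genes of mucous epithelium, type 2 macrophages and antibody-producing cells. Clca1, a secreted regulator of mucus, rose from 57.9 ± 78.9 to 4400 ± 579 (mean ± SD, n = 3), a log2 fold change of 6.95 ± 0.91 (SE). Rnase2a, a ribonuclease of the eosinophil-associated family, rose by 6.20 ± 0.57, the chitinase-like gene Chil4 by 6.09 ± 0.46, Arg1 (arginase) by 6.05 ± 0.44 and the macrophage elastase Mmp12 by 5.29 ± 0.28. The anion exchanger Slc26a4 rose from 70.2 ± 28.9 to 1810 ± 190, and the eosinophil attractant Ccl11 (eotaxin) from 22.9 ± 3.09 to 402 ± 61.9. The other large rises were in AA467197 (5.06 ± 0.30), immunoglobulin kappa Igk (4.66 ± 0.59, and 0.98 on another probe set) and the chemokine Ccl8 (4.10 ± 0.42). The largest falls were in the adhesion gene Nectin3 (-2.27 ± 0.45), the transcription factors Myrf (-2.19 ± 0.27) and Klf15 (-2.16 ± 0.26), and Olfm2 (-2.10 ± 0.29), followed by Tgm5, Sned1, Ang4 and Rmdn1, from -2.09 to -1.84. The others were 2 RIKEN clones. The other probe sets of Rmdn1 were not called (-0.23 and -0.25), and those of Nectin3 had -0.19 and -0.55, not called, and -0.94 and -1.02, called. Sned1 was not called without wild-type PBS replicate 2 or 3 or wild-type HDM replicate 1 or 3 (adjusted p = 0.053 to 0.078), nor Tgm5 without wild-type PBS replicate 2 (0.05).

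By list, 20 of 21 alternatively activated macrophage genes were higher in wild type after HDM and none lower (20 adjusted over the list alone; median 2, camera adjusted p = 7.9e-29), with Alox15 up by 3.69. Goblet cell and mucus genes were higher in 9 of 13 (9 adjusted over the list alone; 4.3e-13), with the gel-forming mucin Muc5ac up by 3.50 and Fcgbp by 2.45. Chitinases were higher in 4 of 5 (4 adjusted over the list alone; 3.1e-07), with Chia1 up by 3 and Chil3 by 2.74. Cell cycle genes were higher in 24 of 34 (28 adjusted over the list alone; median 1, 2e-20), including Mki67 (1.94) and Birc5 (1.77). Macrophage genes were higher in 20 of 30 and lower in 1 (23 and 1 adjusted over the list alone; 3.6e-17), with Gpnmb (3.73, and 0.69 on another probe set, not called), Ctsk (2.55) and Itgax (2.34). Plasma cell and immunoglobulin genes were higher in 9 of 15 (11 higher and 1 lower adjusted over the list alone; 7.5e-11), with Jchain (3.54), Igha (3.49) and the antibody transporter Pigr (3.24). Of 23 chemokines 10 were higher and 4 lower (14 and 4 adjusted over the list alone; 1.5e-07), with Ccl9 up by 3.60. T cell genes were higher in 6 of 20 (11 adjusted over the list alone; 1.5e-08). Dendritic cell and MHC class II genes were higher in 11 of 23 (16 adjusted over the list alone; 5e-10), with Cd83 up by 2.09. Extracellular matrix genes were higher in 15 of 32 (17 higher and 1 lower adjusted over the list alone; 5.1e-07), with Adam8 up by 2.20 and Timp1 by 2.10. These lists were also called with an estimated correlation, with adjusted p from 0.002 (alternatively activated macrophages) to 0.038 (T cells) and 0.043 (extracellular matrix). B cell genes were higher in 11 of 17 (14 higher and 1 lower adjusted over the list alone; 2.8e-11), with Blnk and Pou2af1 each up by 2.07, but the list was not called with an estimated correlation (adjusted p = 0.059). Eosinophil genes were higher in 2 of 4, and in 2 of 4 adjusted over the list alone (0.0013; adjusted p = 0.053 with an estimated correlation). The 2 were Rnase2a and Alox15, which is also in the alternatively activated macrophage list. Of the list's 14 genes 9 were on the arrays. Prg2, Epx and Ccr3 lay under the filter. Tested without it (limma), Prg2 rose by 1.03 (adjusted p = 0.02), while Epx (0.77, 0.091) and Ccr3 (1.06, 0.11) were not called.

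Genes of the gas-exchange surface fell in wild type after HDM. Alveolar type 1 cell genes were lower in 14 of 19 and higher in none (18 adjusted over the list alone; median -0.66, camera adjusted p = 1e-11), among them Akap5 (-1.63 ± 0.28) and the water channel Aqp5 (-1.22 ± 0.12). Endothelial genes were lower in 18 of 27 and higher in 1 (20 and 1 adjusted over the list alone; median -0.67, 4.1e-11), among them Tmem100 (-1.52 ± 0.19) and the angiopoietin receptor Tek (-1.12 ± 0.10). Both lists were called with an estimated correlation (adjusted p = 0.0077 and 0.0099). Alveolar type 2 cell genes were higher in 3 of 22 and lower in 5 (4 and 6 adjusted over the list alone) and the list was not called (median -0.09, adjusted p = 0.56). Club cell genes were lower in 6 of 14 and higher in 1 (6 and 2 adjusted over the list alone; camera adjusted p = 0.012, and adjusted p = 0.23 with an estimated correlation), with the secretoglobin Scgb3a2 falling from 5150 to 1940 and Cyp4b1 from 2420 to 936. In all, 2426 of 31496 probe sets were called (limma, adjusted p under 0.05). Of these 1212 were higher and 1214 lower, 567 and 273 of them at least 2-fold. Camera called 26 of 34 lists, 18 higher and 8 lower, and 14 were called with an estimated correlation. Without wild-type HDM replicate 3 the count was 1387, and without the 3 samples with skeletal muscle signal, which leaves a single wild-type HDM sample, it was 979.

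**Figure D1:**
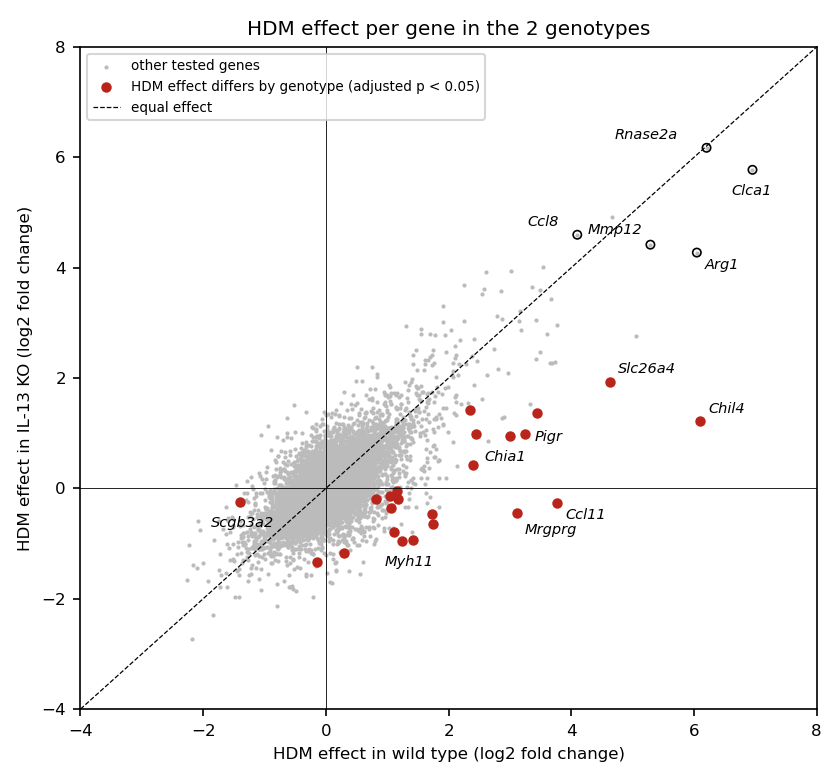
Log2 fold change after HDM in wild type (horizontal axis) and IL-13 KO (vertical axis) for 14477 genes; red points are the 23 genes whose HDM effect differed by genotype, ringed points are large rises without such a call, and the dashed line marks equal effects. Rnase2a (6.20 and 6.17) lies on the line, while Chil4 (6.09 and 1.22) and Ccl11 (3.77 and -0.26) lie far below it.

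IL-13 KO lung also responded to HDM. Rnase2a rose by 6.17 ± 0.57 (log2 ± SE, n = 3 against 3), Clca1 by 5.77 ± 0.91, from 33.1 to 1310, Igk by 4.91 ± 0.59, Ccl8 by 4.6 ± 0.42, Mmp12 by 4.42 ± 0.28 and Arg1 by 4.27 ± 0.44, from 8.44 to 289. Another probe set of Igk rose by 1.14. Antibody-secretion genes Jchain (4.01 ± 0.54) and Mzb1 (3.94 ± 0.28), the mast cell protease Mcpt2 (3.92 ± 0.26) and the protease inhibitor Slpi (3.69 ± 0.31) completed the 10 largest rises. The largest falls were Myrf (-2.73 ± 0.27), Rmdn1 (-2.30 ± 0.35), Acacb (-2.13 ± 0.44), Osbp2 (-1.97 ± 0.36) and the retinol-esterifying enzyme Lrat (-1.96 ± 0.25), followed by Itih2, Igfbp3 and Chst8, from -1.85 to -1.79. The others were a RIKEN clone and a predicted gene. The other probe sets of Rmdn1 were not called (-0.01 and -0.28, adjusted p = 0.99 and 0.65).

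In KO lung alternatively activated macrophage genes were higher in 17 of 21 after HDM (18 adjusted over the list alone; median 1.63, camera adjusted p = 1.8e-20), with Trem2 up by 3.43 and Cd163 by 3.02. Cell cycle genes were higher in 27 of 34 (29 adjusted over the list alone; median 1.37, 2.8e-26), with Cdk1 up by 2.81. Plasma cell and immunoglobulin genes were higher in 10 of 15 (13 adjusted over the list alone; median 2.24, 7.6e-13), with Igha up by 3.60. Goblet cell and mucus genes were higher in 8 of 13 (8 adjusted over the list alone; 2.7e-07), with Muc5ac up by 2.48 and Slc26a4 by 1.93. The list has 19 genes on the arrays, and those under the filter include Itln1, Retnlb, Agr2 and Spdef, chosen after their values were seen. Tested without the filter these rose in wild type after HDM (5.49, 3.95, 3.07 and 1.37). In KO none of them was called (0.14, 0.50, 0.40 and -0.43). Complement and acute phase genes were higher in 10 of 19 and lower in 1 (12 and 1 adjusted over the list alone; 3e-09), with Saa3 up by 2.70 and C1qc by 2.41. Alveolar type 1 cell genes were lower in 12 of 19 (17 adjusted over the list alone; 2.7e-11) and endothelial genes in 17 of 27 with 1 higher (22 and 1 adjusted over the list alone; 1.8e-10). Each of these lists was also called with an estimated correlation, with adjusted p from 0.0017 (cell cycle) to 0.013 (plasma cells). Smooth muscle genes were lower in 8 of 19 and higher in none (10 adjusted over the list alone; median -0.38, 1.4e-05), among them the contractile genes Myh11 (-0.96), Cnn1 (-0.96), Tpm2 (-0.94) and Lmod1 (-0.86), but the list was not called with an estimated correlation (adjusted p = 0.10). These single-gene calls depended on individual samples. Without KO PBS replicate 1 the adjusted p was 0.097 for Myh11, 0.14 for Cnn1, 0.079 for Tpm2 and 0.17 for Lmod1, and without KO HDM replicate 2 it was 0.086, 0.12, 0.069 and 0.15. Without KO HDM replicate 3 it was 0.08, 0.11, 0.082 and 0.052, and some were also lost without KO PBS replicate 2 or 3, KO HDM replicate 1, wild-type PBS replicate 3 or any single wild-type HDM sample. In total 2696 probe sets were called, 1337 higher and 1359 lower. Camera called 26 lists, 17 higher and 9 lower, of which 13 were called with an estimated correlation. Leaving out 1 sample gave 1549 (KO HDM replicate 3), 1593 (KO PBS replicate 3), 1660 (KO HDM replicate 2) or 1699 (KO PBS replicate 1).

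The genes called in the 2 genotypes overlapped. Of 775 genes higher after HDM in wild type and 818 in KO, 501 were shared, against 43.8 for independent lists of those sizes. Of 744 and 767 lower genes 426 were shared, against 39.4. A two-sided Fisher's exact test over genes, which are not independent replicates, gave odds ratios of 77 and 52.5, with p too small to print. Both comparisons used the same estimate of each probe set's spread, which favours calls in both. These odds ratios may therefore be too high. Genes called higher in wild type had a median of 0.97 there and 0.78 in KO, and genes called lower had -0.73 and -0.58. Genes called higher in KO had a median of 0.89 there and 0.74 in wild type, and genes called lower -0.73 and -0.60. The 4 genes called in opposite directions, higher in wild type and lower in KO, were the smooth muscle genes Tpm2 and Myh11, the retinol carrier Rbp4 and the amine oxidase Aoc3. The calls of Tpm2 and Myh11 in KO were lost without KO PBS replicate 1, KO HDM replicate 2 or KO HDM replicate 3, as given above. The shared lower genes were 250 without KO HDM replicate 2, 270 without KO HDM replicate 3, 278 without KO PBS replicate 1 and 280 without KO PBS replicate 3. The 2 effects, which share no arrays, correlated across genes with r = 0.69 (Spearman 0.59).

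**Figure D2:**
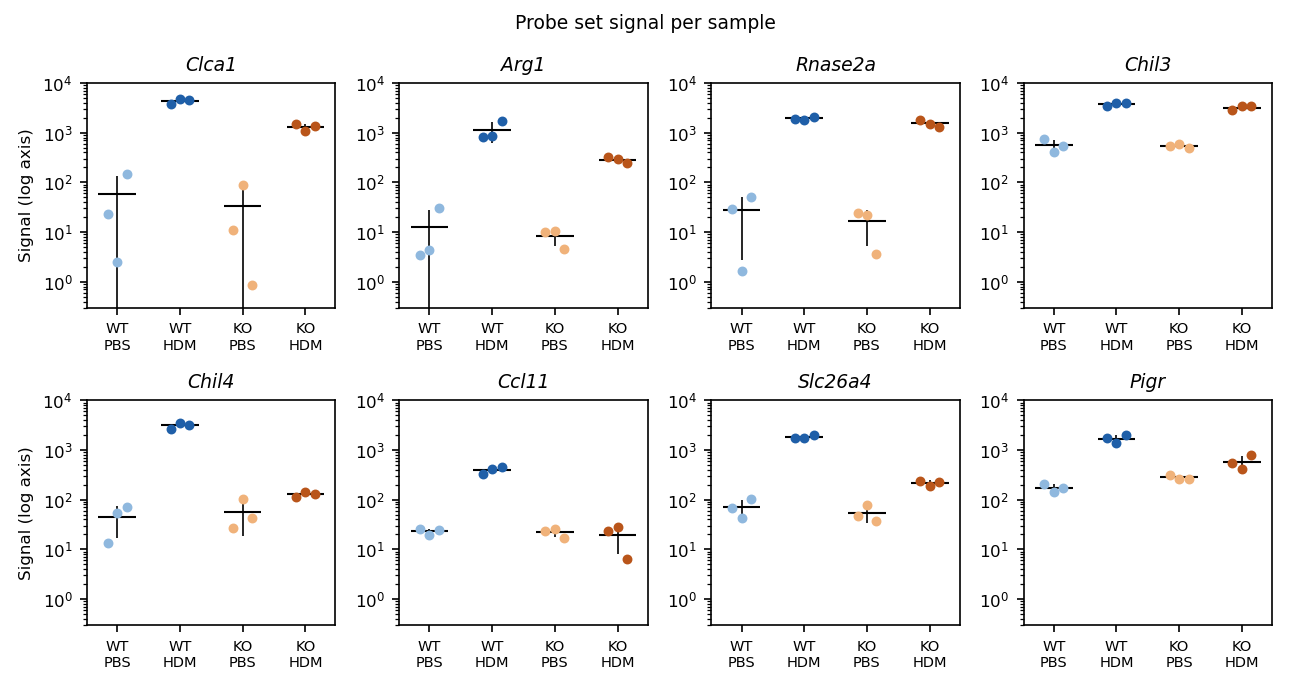
Probe set signal (log axis) of 8 genes in each sample, by group; horizontal bars are means and vertical bars SDs, drawn no lower than the axis floor (n = 3). Clca1, Arg1, Rnase2a and Chil3 rose after HDM in both genotypes, whereas Chil4 reached 3120 in wild type and 127 in KO and Ccl11 reached 402 and 19.1.

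The HDM effect differed between genotypes for a small group of genes, most of which rose after HDM in wild type. In KO some of these rose less, Tpm2, Rbp4, Myh11 and Aoc3 fell, and others, such as Ccl11 and Chil4, were not called. The largest difference among probe sets that passed the filter was in Chil4, which went from 45.6 ± 29 to 3120 ± 392 in wild type and from 57.2 ± 38.8 to 127 ± 15.2 in KO, an interaction of -4.87 ± 0.64 (adjusted p = 0.016). Ccl11 was not called in KO, with 22 ± 4.2 after PBS and 19.1 ± 11.2 after HDM (-4.02 ± 0.44, adjusted p = 0.0076). Epithelial genes with smaller rises in KO were Slc26a4 (-2.69 ± 0.39), Pigr (-2.26 ± 0.30, and -2.66 on another probe set), the acidic chitinase Chia1 (-2.05 ± 0.26), the amino acid transporter Slc6a20a (-2.08 ± 0.30) and Fcgbp (-1.47 ± 0.23). Contractile genes were Tpm2 (-2.36 ± 0.32), Myh11 (-2.19 ± 0.33), Actg2 (-2.19 ± 0.25), Tagln (-1.42 ± 0.19), Acta2 (-1.18 ± 0.19) and Synpo2 (-1.02 ± 0.16). Other probe sets of Tpm2 (-0.73 and -1.52) and Synpo2 (-1.14 to -0.02) were not called. Acta2, smooth muscle actin, rose from 1230 to 2540 in wild type and was not called in KO, with 1190 and 1080. The gene with a positive interaction was Scgb3a2 (1.16 ± 0.15, adjusted p = 0.016), which fell from 5150 to 1940 in wild type, while in KO it had 5150 and 4330 and was not called.

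The remaining called genes were Mrgprg (-3.55), Rbp4 (-2.38), the actin-severing Scin (-1.98), Aoc3 (-1.92), the aldehyde oxidase Aox3 (-1.46), carbonic anhydrase Car2 (-1.37), Ahcyl2 (-1.20, and -0.55 and -0.85 on other probe sets, not called), Evc2 (-1.18) and the integrin Itgax (-0.92). Aox3 and Evc2 were not called in wild type after HDM (0.29 and -0.15) and fell in KO (-1.17 and -1.33). The 23 genes came from 27 called probe sets, 1 higher and 26 lower, of which 2 had no single gene. Gkn3 was called on a probe set that does not represent it in the gene-level table (-3.69, chosen after its values were seen). Arg1 (-1.77 ± 0.62, adjusted p = 0.77), Il33 (-0.79 ± 0.20, 0.47) and Mcpt2 (1.30 ± 0.36, 0.61) were not called. At an unadjusted p under 0.05 there were 1797 probe sets.

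By list, 6 of 19 smooth muscle genes had a lower HDM effect in KO (11 lower and 1 higher adjusted over the list alone; median -0.68, camera adjusted p = 4.8e-16). Chitinases had 2 of 5 lower (3 adjusted over the list alone; median -0.83, 1.3e-06) and goblet cell and mucus genes 2 of 13 (3 adjusted over the list alone; median -0.35, 4.6e-06). The goblet cell values leave out Itln1, Retnlb, Agr2 and Spdef, which lay under the filter. Cell cycle genes had a higher HDM effect in KO as a list (median 0.36, 1.3e-06), with 0 of 34 members called by limma, or adjusted over the list alone; Birc5 (1.01 ± 0.31, adjusted p = 0.66) and Rrm2 (0.68 ± 0.21, 0.66) had the smallest p. These 4 of 13 called lists were also called with an estimated correlation. Its adjusted p was 0.027 for smooth muscle, chitinases and goblet cells and 0.045 for cell cycle. In wild type itself 6 smooth muscle genes were higher after HDM and 2 lower (9 and 3 adjusted over the list alone; median 0.40, camera adjusted p = 0.00077, and adjusted p = 0.16 with an estimated correlation). In the model with the skeletal muscle score, the interaction median of the smooth muscle list was -0.58, without the 3 samples with skeletal muscle signal it was -0.73, and with the actin ratio in the model it was -0.93.

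Calls for single genes depended on which samples were included. Leaving out 1 sample gave 6 probe sets (wild-type HDM replicate 1 or KO HDM replicate 3), 7 (KO HDM replicate 1), 8 (wild-type HDM replicate 2 or 3, or KO HDM replicate 2), 9 (KO PBS replicate 1), 13 (wild-type PBS replicate 1 or KO PBS replicate 2), 15 (wild-type PBS replicate 2), 17 (KO PBS replicate 3) or 19 (wild-type PBS replicate 3). Without the 3 samples with skeletal muscle signal 1 probe set was called. The log2 interactions of the 23 genes were then 78.8% to 113.7% of those from all samples, with adjusted p from 0.051 for Rbp4 to 0.53 for Scin. Chil4 was -5.12 in that fit (adjusted p = 0.21, with 0.01 to 0.21 over all alternatives) and Myh11 -1.84 (0.38, with 0.029 to 0.38). With the actin ratio in the model 8 probe sets were called. Aox3, Actg2, Rbp4 and Ccl11 were the 4 genes called whichever single sample was left out. Of these, Aox3 was not called with the actin ratio in the model.

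**Figure D3:**
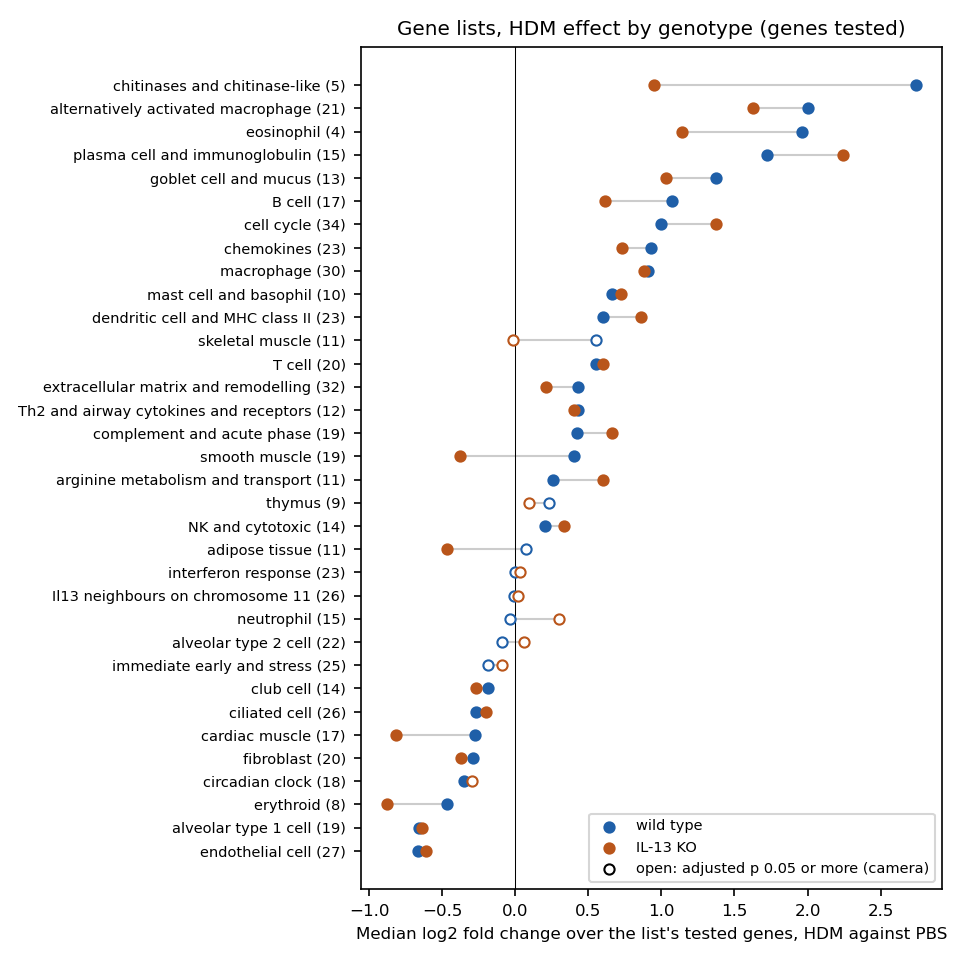
Median log2 fold change after HDM over the tested genes of each list in wild type (blue) and IL-13 KO (orange), with the number of genes in brackets; filled points were called by camera. The smooth muscle list had medians of 0.40 and -0.38, and the alternatively activated macrophage list 2 and 1.63. With an estimated correlation 14 of 26 lists stayed called in wild type and 13 of 26 in KO. The smooth muscle list did not stay called in either genotype.

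Without HDM few genes were called between KO and wild type. Xaf1, a gene known for its response to interferon, had 1750 in KO and 148 in wild type (3.47 ± 0.15, adjusted p = 5.8e-07, n = 3 each), but a second probe set of Xaf1 was lower in KO (-2.54 ± 0.28, 0.0061). The collagen gene Col23a1 was higher (0.80 ± 0.10, 0.016) and Rin3 lower (-0.89 ± 0.11, 0.013). Other probe sets of Col23a1 were not called (0.43 and 0.97). Neither was called without wild-type PBS replicate 2 or 3 or KO PBS replicate 3, nor was Col23a1 without KO PBS replicate 1 or Rin3 without KO PBS replicate 2. The adjusted p was 0.073, 0.07, 0.084 and 0.095 for Col23a1 in these fits, and 0.073, 0.055, 0.06 and 0.054 for Rin3. On probe sets that do not represent their gene in the gene-level table, chosen after their values were seen, Cux2 (4.15 ± 0.41), Wdr53 (2.86 ± 0.23) and Scd2 (1.44 ± 0.19) were higher and Golm2 (-1.94 ± 0.22), Trim16 (-1.82 ± 0.21), Pi4k2b (-1.45 ± 0.20) and Lyz1 (-0.83 ± 0.11) lower. In all, 12 probe sets were called, 6 in each direction, and 2143 had an unadjusted p under 0.05. The count was 20 without wild-type PBS replicate 1, 6 without KO PBS replicate 3, 7 with set A alone and 5 without the samples with skeletal muscle signal. Camera called 10 lists, 6 higher and 4 lower, whereas camera with an estimated correlation and fry each called 0. B cell genes, the list with the smallest p, had 0 of 17 members called (2 higher adjusted over the list alone; median 0.39, 6.2e-07, and adjusted p = 0.34 with an estimated correlation).

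After HDM, KO lung had less signal than wild type for many of the same kinds of genes, and more for others. Chil4 (-4.54 ± 0.46), Ccl11 (-4.07 ± 0.31), Slc26a4 (-3.02 ± 0.27), Chia1 (-2.73 ± 0.18) and Rgs5, a regulator of G-protein signalling in pericytes (-2.38 ± 0.20, and -0.62 on another probe set, not called), were lowest relative to wild type, followed by AA467197 (-2.31), Scin (-2.28), Mrgprg (-2.23), Aoc3 (-2.10) and Actg2 (-2.10). Rgs5 was also lower in KO after PBS, though not called there (-1.05, adjusted p = 0.16), and its interaction was not called (-1.33, 0.22). The mucin Muc5ac had 262 ± 28.4 in wild type and 114 ± 8.39 in KO (-1.15 ± 0.19, adjusted p = 0.018), a call lost without any single HDM sample (0.051 to 0.087). The alarmin Il33 had 644 and 304 (-1.07 ± 0.14, 0.0045). Genes higher in KO were Xaf1 (3.32 ± 0.15), the paraoxonase Pon1 (1.68 ± 0.18), the IgA heavy chain Igha (1.66 ± 0.28), with 4910 in KO and 1520 in wild type, Slamf7 (1.24 ± 0.24), Scgb3a2 (1.16 ± 0.11) and Fpr2 (1.15 ± 0.18), then Bex2 and Thbs3 (1.12 and 1.09) and 2 RIKEN clones. Igha had a difference of like size after PBS, 408 in KO and 130 in wild type (1.55, adjusted p = 0.14, not called; interaction 0.11, adjusted p = 0.99). After HDM Igha was not called without wild-type HDM replicate 1 (adjusted p = 0.079) or 2 (0.082) or KO HDM replicate 1 (0.071) or 3 (0.1). Slamf7 was lost without any single HDM sample (0.067 to 0.21), Mrgprg without wild-type HDM replicate 2 (0.12) or 3 (0.087) or KO HDM replicate 1 (0.07), and Fpr2 without KO HDM replicate 3 (0.07). Bex2 was lost without wild-type HDM replicate 1 (0.052) or KO HDM replicate 1 (0.064), and Thbs3 without wild-type HDM replicate 3 (0.052) or KO HDM replicate 1 (0.074) or 3 (0.087). Of the 40 named genes, 30 were not called without the samples with skeletal muscle signal, among them Chil4, AA467197, Scin, Mrgprg, Il33, Muc5ac, Pon1 and Igha, and 0 changed sign. With the skeletal muscle score in the model 19 were not called, Mrgprg, Muc5ac and Igha among them. With the actin ratio in the model 13 were not called, among them Mrgprg, Muc5ac, Slamf7, Fpr2, Bex2 and Thbs3.

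Smooth muscle genes were lower in KO in 10 of 19 after HDM (13 lower and 1 higher adjusted over the list alone; median -0.88, camera adjusted p = 1.9e-18). Goblet cell and mucus genes were lower in 4 of 13 (6 adjusted over the list alone; median -0.62, 1.7e-12), and chitinases in 3 of 5 (3 adjusted over the list alone; median -0.74, 3.6e-08). These 3 of 16 called lists were also called with an estimated correlation (adjusted p = 0.017, 0.0064 and 0.015). Extracellular matrix genes were lower in 5 of 32 (13 lower and 2 higher adjusted over the list alone; 1.4e-08), with Thbs1 (-1.45) and Ccn2 (-1.23), but the list was not called with an estimated correlation (adjusted p = 0.072). Neither gene was called without the samples with skeletal muscle signal or with the skeletal muscle score in the model. Skeletal muscle genes had a median of -0.94 with 0 of 11 called (0 adjusted over the list alone; 2.2e-06, and adjusted p = 0.20 with an estimated correlation), the wild-type HDM samples being 2 of the 3 with high skeletal muscle signal. Adipose tissue genes (median -0.56, 6.9e-06, 0 of 11 called, 2 lower adjusted over the list alone) and cardiac muscle genes (-0.31, 3.2e-05, 1 of 17 lower, 1 adjusted over the list alone) were also lower as lists, but not with an estimated correlation (adjusted p = 0.17 and 0.30). Of the 16 lists 8 were higher and 8 lower in KO, and none of the higher ones was called with an estimated correlation. The higher ones included plasma cells (median 0.55, camera adjusted p = 4.3e-05), cell cycle (0.22, 4.4e-05), T cells (0.4, 5.5e-05) and ciliated cells (0.29, 0.00012). Further higher lists were NK cells (0.002), mast cells (0.0055), interferon response (0.01) and alveolar type 1 cells (0.019). In all, 144 probe sets were called (limma), 45 higher and 99 lower. The count was 59 without KO HDM replicate 3, 76 without KO HDM replicate 1 or wild-type HDM replicate 2 and 94 without KO HDM replicate 2. It was 30 without the samples with skeletal muscle signal and 51 with the skeletal muscle score in the model.

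**Figure D4:**
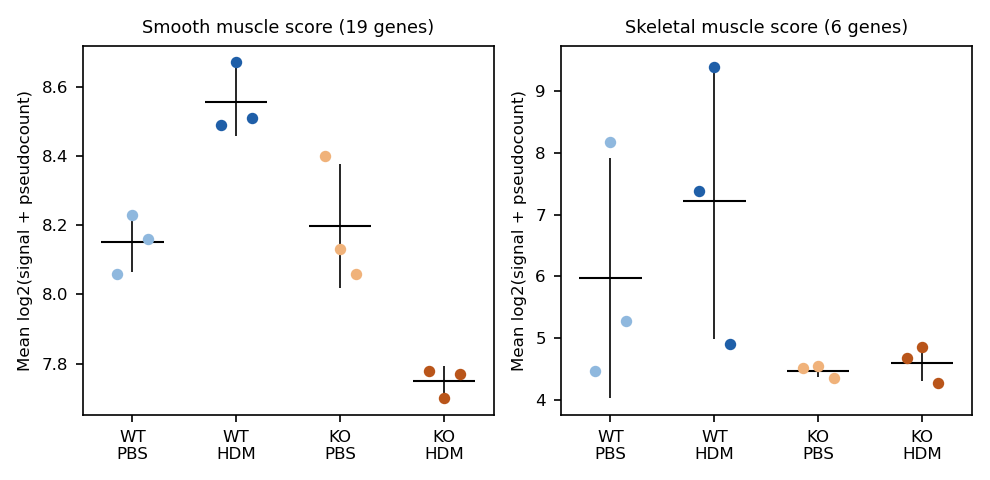
Mean log2(signal + pseudocount) over smooth muscle genes (left) and skeletal muscle genes (right) in each sample, with group means and SDs (n = 3). The smooth muscle score was 8.49 to 8.67 in wild type and 7.7 to 7.78 in KO after HDM, while the skeletal muscle score was above 7 in 3 wild-type samples only.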

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

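The 100 splits of the samples and the test with airway cartilage genes were written before their results were seen. The tests with the skeletal muscle score, with the actin ratio and with ciliated cell genes, and the choice of Itln1, Retnlb and Duoxa1, came after the values were seen.

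The response of 23 genes to HDM differed between genotypes in a test of the difference itself. Relative to wild type the HDM effect in KO was lower for Chil4 (-4.87), Ccl11 (-4.02), Mrgprg (-3.55), Slc26a4 (-2.69), Rbp4 (-2.38), Tpm2 (-2.36), Pigr (-2.26), Myh11 (-2.19), Actg2 (-2.19), Slc6a20a (-2.08), Chia1 (-2.05), Scin (-1.98), Aoc3 (-1.92), Fcgbp (-1.47), Aox3 (-1.46), Tagln (-1.42), Car2 (-1.37), Ahcyl2 (-1.2), Acta2 (-1.18), Evc2 (-1.18), Synpo2 (-1.02) and Itgax (-0.92). It was higher for Scgb3a2 (1.16). In all 27 probe sets were called. Of 100 splits that regrouped the samples, 3 gave as many, the real one included, under the limit of 5% set beforehand. The highest other split, which called 118, exchanged the genotype labels of all HDM samples and so measured a genotype difference common to both treatments, a structure of the samples. The other, which called 27 like the real one, exchanged these labels too and those of 1 pair of PBS samples. A split that called 25 kept the HDM groups and mixed the PBS samples. These 3 splits all kept the HDM samples of a genotype together. The count therefore follows the grouping of the HDM samples, and the splits do not exclude chance as the source of the interaction calls.

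Among gene lists, medians of the difference were below 0 for chitinases (-0.83), smooth muscle (-0.68), adipose tissue (-0.68), alternatively activated macrophages (-0.38), cardiac muscle (-0.37), goblet cells and mucus (-0.35), erythroid cells (-0.35), B cells (-0.31), macrophages (-0.09) and extracellular matrix (-0.08). They were above 0 for plasma cells and immunoglobulins (0.48), cell cycle (0.36) and mast cells and basophils (0.3). Of the 13 lists, 9 were not called with an estimated correlation, with adjusted p = 0.15 for alternatively activated macrophages, 0.48 for B cells, macrophages and cardiac muscle, 0.45 for plasma cells, extracellular matrix and adipose tissue, 0.18 for mast cells and 0.19 for erythroid cells. As many lists as in the real split were called in 8 of 100 splits, with 16 in the highest other, so chance cannot be excluded for the number of lists.

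Some probe sets under the filter had strong signal in wild-type HDM samples and little elsewhere. Itln1, an intelectin of mucous cells, had 420 ± 18.6 in wild type after HDM and 2.98 ± 0.819 in KO after HDM, with 2.54 and 2.08 after PBS (SD, n = 3). Retnlb, a resistin-like gene, had 157 and 7.25, and Duoxa1, a maturation factor of an epithelial oxidase, 120 and 12. Tested without the filter their interactions were -5.35 ± 0.26 (adjusted p = 3.7e-06), -3.45 ± 0.30 (0.001) and -2.26 ± 0.32 (0.029). The goblet cell genes Agr2 (162 and 17.1) and Spdef (65.2 and 12.9) were not called there, with -2.67 (0.16) and -1.80 (0.46). Itln1, Retnlb, Agr2 and Spdef belong to the goblet cell and mucus list, whose counts, medians and tests do not include them.

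The smooth muscle list was weighed as a pattern, since muscle tissue varied between samples. The mean over its 19 genes had an interaction of -0.85 ± 0.13. With the skeletal muscle score in the model it was -0.81 ± 0.12, which argues against skeletal muscle in some wild-type samples as the whole source. With the ratio of 5' to 3' actin signal, which was lower in KO than in wild type after HDM, it was -0.92 ± 0.15, which argues against a trend with RNA integrity as the whole source. A smaller share of airway in the KO HDM samples was taken to bring other airway genes to -0.43 or below. Ciliated cell genes had 0.09 ± 0.11 (26 genes), which argues against it only if ciliated genes do not respond themselves. Their median change after HDM was -0.27 in wild type and -0.20 in KO. A ciliated response that offsets a smaller share of airway therefore remains open. Airway cartilage genes had -0.06 ± 0.14, but 12 of the 17, Col2a1 among them (4.59 to 15.2), lay under the filter, so cartilage-bearing airway remains open. Adipose tissue and cardiac muscle in some wild-type samples were not tested as a source and remain open too. An effect of the genotype on contractile gene expression or on the amount of smooth muscle remains open, and these could not be separated here.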

How the results depend on the processing

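Leaving out the samples with skeletal muscle signal and adding a skeletal muscle score or the actin ratio were chosen after seeing the data; the replicate-number block and the other settings were not. No result reversed. Of 300 calls of named genes, those lost were 24 without the intensity trend, 20 without the filter, 11 of 297 with the smaller pseudocount, 4 with quantile normalization, 30 with the block, 38 with the score, 45 with the actin ratio, 2 of 250 with the stricter filter, 94 without the skeletal muscle samples and 79 in at least 1 of the fits that left out a single sample. Counts of called probe sets stayed within 1.5 times of those reported except the following, whose cause was not tested unless named. For the interaction, 27 became 17 with the smaller pseudocount, with the stricter filter and without trend, 11 with the replicate block and 8 with the actin ratio. KO against wild type after PBS had 7 with set A alone, which tests fewer probe sets. Without the skeletal muscle samples, fewer samples left 979 (wild type HDM effect), 1 (interaction), 5 (KO against wild type after PBS) and 30 (after HDM), the last being 51 with the score; the lone wild-type HDM sample is then assumed to vary like the others. Leaving out each sample in turn, which leaves fewer samples, gave 1387 to 2311 for HDM in wild type, 1549 to 2807 in KO, 6 to 19 for the interaction, 6 to 20 after PBS, 59 to 153 after HDM, 349 to 453 shared higher genes and 250 to 380 shared lower genes. Called lists were 25 to 27, 25 to 26, 10 to 16, 7 to 11 and 14 to 18. With an estimated correlation, 14, 13, 4, 0 and 3 lists were called in the same order. Fry called 4 for the interaction, 0 after PBS and 10 after HDM. Replicate numbers showed no sign of pairing: 18 pairs of samples with a number in common correlated from -0.09 to 0.17, and 4 of 12 samples matched their own number best. Signal over background limits genes such as Il13, Il5, Itln1 and Retnlb, whose low signal in most groups puts them under the filter and shrinks their fold changes.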

Other observations

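The splits of the samples were written before their results were seen. The tests of a segment near Il13, of probe-level differences and of dilution were chosen only after the result was seen.

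HDM moved several groups of genes not described above. The arginine list was higher in 4 of 11 in wild type and 5 of 11 in KO (4 and 6 adjusted over the list alone; camera adjusted p = 0.00024 and 1.6e-05), and was called in both with an estimated correlation. Its adjusted p with an estimated correlation was 0.013 and 0.0081. Besides Arg1 the list included Gatm (1.68), the arginine transporter Slc7a2 (1.26) and Arg2 (1.25) in wild type. Mast cell and basophil genes were higher in 4 of 10 and lower in 1 in wild type (5 and 1 adjusted over the list alone; 0.02, and adjusted p = 0.10 with an estimated correlation) and 5 and 1 in KO (5 and 2 adjusted over the list alone; 0.0043, and adjusted p = 0.062 with an estimated correlation). Mcpt2 reached 177 ± 18.5 in wild type and 435 ± 30.8 in KO, and the tryptase Tpsb2 55.6 ± 16.3 and 149 ± 14.5 (SD, n = 3). Mcpt4, under the filter and chosen after its values were seen, had 21.5 and 120. Th2 and airway cytokine genes were higher in 3 of 12 and 1 of 12 (6 and 3 adjusted over the list alone; 0.0011 and 0.0043), with adjusted p = 0.07 and 0.11 with an estimated correlation. Il33 rose by 1.37 in wild type and 0.59 in KO, and was not called in KO without KO PBS replicate 1 (adjusted p = 0.075) or 2 (0.066) or KO HDM replicate 1 (0.092) or 3 (0.057).

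Clock genes included falls of the repressors Nr1d1 (-1.61 ± 0.24), Ciart (-1.38 ± 0.33) and Nr1d2 (-1.32 ± 0.26) in wild type, Ciart not being called without wild-type PBS replicate 1 (adjusted p = 0.086) or 3 (0.073) or wild-type HDM replicate 1 (0.074). The list had 4 of 18 lower and 2 higher (7 and 2 adjusted over the list alone; 0.032, and adjusted p = 0.14 with an estimated correlation). In KO 2 of 18 were lower (2 lower and 1 higher adjusted over the list alone) and the list was not called (0.16). Immediate early and stress genes were not called as a list (0.054 and 0.23), with 7 lower and 3 higher of 25 in wild type (8 and 3 adjusted over the list alone), among them Dusp1 (-1.17), and 3 and 2 in KO (3 and 2 adjusted over the list alone). The time of day of tissue collection was not given in the sources used here. Erythroid genes were lower in 3 of 8 and higher in 1 in wild type (4 and 1 adjusted over the list alone; 0.012, and adjusted p = 0.17 with an estimated correlation) and lower in 5 of 8 in KO (5 adjusted over the list alone; 5.7e-06, also called with an estimated correlation), with Alas2 at -1.27 and -1.68. In KO the adjusted p with an estimated correlation was 0.04.

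Other lists are given in the order wild type, KO. Ciliated cell genes were lower in 4 and 2 of 26 (6 and 3 adjusted over the list alone; 0.00019 and 0.0043), with adjusted p = 0.089 and 0.17 with an estimated correlation. Fibroblast genes were lower in 4 and 9 of 20 and higher in 1 and 3 (0.021 and 0.029), with adjusted p = 0.18 and 0.20 with an estimated correlation. NK and cytotoxic genes were higher in 1 and 3 of 14 (0.016 and 0.015), with adjusted p = 0.14 and 0.15 with an estimated correlation. Cardiac muscle genes, which belong to heart and to the sleeves of pulmonary veins, were lower in 4 and 8 of 17 (5 and 9 adjusted over the list alone; 0.02 and 2e-06), with Myh6 at -1.22 and -1.44 and adjusted p = 0.49 and 0.17 with an estimated correlation. Skeletal muscle genes had 0 of 11 called in both (0.27 and 0.65), with the 3 high samples spread over both wild-type groups. Adipose genes had 0 of 11 called (0.51 and 0.029, and adjusted p = 0.80 and 0.40 with an estimated correlation). Neutrophil genes (0.42 and 0.15), interferon response genes (0.85 and 0.28), thymus genes (0.24 and 0.18) and the neighbours of Il13 (0.85 and 0.35) were not called. The neutrophil list in wild type is one in which the median (-0.04) and the mean (0.08) differed in sign. Xist, on the X chromosome and expressed from the inactive copy, had a signal of 883 to 1780 in every sample, and the Y-linked Eif2s3y at most 5.69. All samples thus had the expression pattern of female mice, so sex did not differ between the groups.

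The number of splits of 6 samples into 3 and 3 is 10, too few for a share under 0.05, and in each comparison 1 split gave as large a number, the real one. The real number of probe sets and the highest of the other splits were 2426 and 2 for HDM in wild type, 2696 and 1 for HDM in KO, 12 and 5 for KO against wild type after PBS, and 144 and 2 after HDM. For gene lists they were 26 and 20, 26 and 15, 10 and 5, and 16 and 12.

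Some differences between genotypes were present with and without HDM. Called in the mean of both treatments, with the same sign and an unadjusted p under 0.05 in each, were 71 probe sets, 31 higher and 40 lower in KO, for 53 genes. Of these genes 7 lay within 500 genes on either side of Il13 (13.2%, against 2.31% of tested genes; odds ratio 6.54, two-sided Fisher's exact p = 0.00021): Anxa6, Cfap52, Col23a1, Myh10, Ndel1, Specc1 and Trim16. The list of the nearest neighbours of Il13 itself was not called between genotypes, with 0 of 26 genes after PBS (median -0.05, adjusted p = 0.6) and 0 of 26 after HDM (0.06, 0.69). The enrichment could come from a chromosome segment that came with the knockout allele from another strain. The nearest neighbours of Il13 cannot decide this. Of 14477 genes only 3 were called after PBS and 97 after HDM, and camera looks for a shift in a shared direction. Another probe set of the gene bore out 57.5% of genotype calls (23 of 40) and 75.3% of a subset of HDM calls (140 of 186; Fisher's exact p = 0.032). The subset held, for each genotype call, the 5 HDM calls nearest to it in absolute log2 change, each counted once, and the difference may depend on this choice. Probe sets of a gene disagreed in Xaf1, so sequence differences under single probe sets may contribute. The strains were not given in the sources used here, and both explanations remain open. An effect of the missing IL-13 itself was not tested and remains open too. The called genes include Chia1 (-1.70 in the mean of both treatments) and Fcgbp (-1.20), whose HDM effect also differed between genotypes.

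The fall of alveolar type 1 and endothelial genes after HDM could come from dilution of resident cells by incoming cells. Uniform dilution would lower alveolar type 2 genes alike. The 17 type 2 genes found in no other list changed by -0.05, against -0.69 for type 1 and -0.55 for endothelial genes. Relative to the type 2 genes the changes were -0.64 and -0.51 (two-sided exact permutation test within genotype, p = 0.005 for each, the smallest that 400 regroupings can give), which argues against uniform dilution as the whole cause. A rise in type 2 gene expression that offsets dilution remains open.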
